A study of Mus musculus with 16 samples.

How the data were processed

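Sorted VE-cadherin-positive cells of mouse embryos were profiled on 16 arrays, 2 for each of 8 groups made by tissue, CD45 gate and genotype. Groups came from the sample titles. The titles of the embryo CD45− transgenic samples name only Tie-2, and these were taken as the Tie-2-Etv2 group. Per the labels' protocols, cells were sorted by flow cytometry, RNA was purified with a microelute kit and labelled with Cy3 by the low input protocol of the array's maker, and the animals were of mixed strain background. The scanner files held spot intensities made with Agilent Feature Extraction 10.7, per the file headers and the submitters' processing notes: processed intensities were background-subtracted and detrended within each array, with surrogate values for spots at background, and were not normalized between arrays. Each array had 62976 spots, 59305 of them not controls, for 55681 probes.

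The deposited value table held log2 values whose making is not given in the sources used here. Set against the scanner values, each column was the log2 of the processed intensity shifted by a constant per array and centred, per probe, on the median of the 4 arrays of a tissue and gate. The lowest correlation of array differences between table and scanner files was 0.999918. The scale, centring and direction were thus found, while the reason for the constants stays unknown. Column medians, for control and then Tie-2-Etv2 arrays, were 0.175, −0.0945, 0.0281 and −0.0323 in embryo CD45− cells. They were 0.166, −0.0837, 0.00548 and −0.0324 in embryo CD45+ cells. In the yolk sac they were 0.0851, −0.183, 0.0156 and −0.00454 in CD45− cells. In its CD45+ cells they were 0.147, 0.00331, −0.00892 and −0.121. As the table was centred within tissue and gate, it was used as an alternative only for the genotype comparisons.

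Replicate spots of a probe were averaged after leaving out control spots and outlier spots, and 87 probes with an array lost in this way were not used. Levels were the log2 of the processed intensity minus the 75th percentile of the array. A probe was kept if well above background on both arrays of at least 1 group, which kept 34126 probes. Accessions named 26582 probes through a RefSeq table of assembly GRCm38.p6, used for names only. Symbols named 2602, other accessions 38 and synonyms 474, and 25985 probes had no symbol. The brightest probe stood for a gene, which gave 24578 genes (16532 with a symbol). Of 279 gene values available to the text 66 had several probes, and 3 had a probe of opposite sign, all named with both values in the report. Coordinates are on mm9, as in the files.

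One model over all 16 arrays was fitted with limma 3.58.1 (R 4.3.3), with lmFit and eBayes on group means, 8 residual and 2.29 prior degrees of freedom and Benjamini-Hochberg adjustment per comparison, at a threshold of 0.050. Pooling the spread over groups was chosen because 2 arrays per group give little of their own. All adjusted p-values for genes come from limma, two-sided, and an error after a difference is the SE of the fit. Differences of CD45+ and CD45− effects, or of yolk sac and embryo effects, were contrasts of the same fit. Where a gene was not well above background on any array of a group, the difference is given as a bound: the mean of the brighter group against the dim group's mean of, per array, the higher of the lowest signal well above background and its own signal. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.

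Gene lists, 29 in number, were fixed before the data were examined: pan-endothelial genes, early Etv2-dependent blood and endothelial regulators, arterial endothelial genes, venous and capillary endothelial genes, lymphatic endothelial genes, angiogenic sprouting genes, Notch pathway genes, vascular basement membrane genes, blood-brain-barrier endothelial genes, hemogenic endothelium and stem cell genes, pan-leukocyte genes, macrophage genes, granulocyte and mast cell genes, megakaryocyte and platelet genes, primitive erythroid genes, erythroid genes, lymphoid genes, mesenchymal and mural cell genes, endothelial-to-mesenchymal transition genes, yolk sac endoderm and liver genes, neural genes, cardiac and skeletal muscle genes, epithelial genes, ETS family factors, cell cycle genes, p53 response and apoptosis genes, dissociation stress genes, interferon response genes and hypoxia and glycolysis genes. Some lists share genes with others: of 43 tested pan-endothelial genes 19 also stood in another list. Each list of at least 5 tested genes was tested with camera at a preset inter-gene correlation of 0.010, with an estimated correlation and fry as alternatives, adjusted over the lists of a comparison. List p-values are camera's, and the adjusted p with an estimated correlation is given as the estimated-correlation p. Where lists follow one another, each has its median and, in brackets, for comparisons over both slides the medians on the embryo and on the yolk sac arrays alone, then the estimated-correlation p, medians that an alternative moved by over 1.5 times, and the adjusted p at which a call was lost.

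Genes were named by a rule fixed before the data were examined: Etv2, Cdh5, Ptprc and Tek everywhere; the 10 largest rises and falls among passing genes whose arrays did not overlap and that were well above background in the higher group; up to 4 members of each list with the smallest p; and hemoglobin, pan-endothelial and hemogenic endothelium genes anywhere. Which of these genes appear in the text, and in which comparison a list is described, was chosen after values were seen. Values of some items are not reported here.

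Per the scanner files, the embryo arrays lay on 1 slide and the yolk sac arrays on the other, so slide and tissue cannot be told apart. The gates lay in separate columns of each slide. Genotype and gate comparisons lie within a slide. Medians on each slide are given for the lists described for the average effect, the difference between gates and the gates in controls. Alternatives fixed before the data were examined were quantile normalization, normexp background correction (offset 50), a scaling percentile over probes above background on all arrays (detected-probe scaling), other filters on dim probes (55594 probes without one, 23491 well above background on all arrays, the strict filter), the mean over the probes of a gene (the probe mean), a trended robust prior, the deposited value table, smaller sets of arrays (the 4 arrays of a comparison, or the 8 of a slide), the replicate number as a block and leaving out each array. Arrays left out are written by tissue (E for embryo, Y for yolk sac), gate (− or +), genotype (C for control, Tg for Tie-2-Etv2) and replicate number. Pairs in brackets after higher and lower calls are those under alternatives, the block aside, that moved either count by over 1.5 times or their share by over 10 points, or turned the majority. The lone array then left in a group is assumed to vary like the other groups.

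Other scalings moved the median difference of all genes by over 0.1 in these comparisons. For yolk sac CD45− cells it was 0.18, against 0.06 with quantile normalization, 0.02 with normexp and −0.14 with detected-probe scaling. For yolk sac CD45+ cells it was 0.04, against −0.07 with normexp. For the difference between gates it was −0.07, against 0.05 with detected-probe scaling, and between tissues 0.14, against −0.03 with normexp and −0.09 with detected-probe scaling. For the gates in controls it was 0.14, against −0.01 with quantile normalization and −0.10 with detected-probe scaling, and for the tissues in CD45− controls −0.12, against −0.01 with normexp.

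The fits were tested on simulated data with 67 genes changed 2-fold, 67 changed 4-fold and 66 changed 8-fold among 24578. For the embryo CD45− comparison 23.9% at 2-fold, 68.7% at 4-fold and 84.8% at 8-fold were recovered, with 8 false calls, and for the average over populations 74.6% at 2-fold, 94% at 4-fold and 97% at 8-fold, with 9. For embryo CD45− a list shifted by 1 log2 unit passed camera (adjusted p = 3.63e-14) with 0 other lists called, which need not hold for correlated genes. In simulated mixtures holding 20% of the other gate's RNA, the test of admixture excluded a common share for 8.11%, 2.78%, 7.14% and 7.41% of genes in the 4 populations. That test was run on the real values before its simulation.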

Results

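Transcript levels were measured in VE-cadherin-positive cells sorted from mouse embryos at E11.5, on 16 Agilent 1-colour expression arrays with 1 cell sample per array. Cells had been sorted by VE-cadherin, the endothelial junction protein encoded by Cdh5, and by CD45, the leukocyte surface protein encoded by Ptprc. VE-cadherin-positive cells without CD45 (CD45− cells) and with CD45 (CD45+ cells) came from the embryo proper and from the yolk sac, of control animals and of animals labelled Tie-2-Etv2. Etv2 is an ETS-family transcription factor needed for the earliest blood and endothelial cells of the embryo, and Tie-2 is the endothelial receptor encoded by Tek. The 8 groups held 2 arrays each. On each array 50.6% to 59.9% of probes were well above background and 0 spots were saturated. The arrays of a group correlated at 0.975 to 0.992 across 24578 genes, which are not independent replicates. The number of arrays limits the precision. The labels do not say whether the samples of a group came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical. Levels are log2 signals relative to the 75th percentile of each array, and differences are on the log2 scale with their standard error (SE).

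Etv2 lay higher on both Tie-2-Etv2 arrays than on both control arrays in each of the 4 populations. In yolk sac CD45− cells it rose from −2.78 ± 0.25 (mean ± SD) to 3.58 ± 0.45, a difference of 6.36 ± 0.96 (SE, adjusted p = 0.00051), and in yolk sac CD45+ cells by 6.08 ± 0.96 (adjusted p = 0.000837; lost at adjusted p = 0.0638 on the 4 arrays alone). The embryo differences did not pass the test: they were 2.50 ± 0.96 in CD45− cells (adjusted p = 0.574) and 3.09 ± 0.96 in CD45+ cells (adjusted p = 0.124). The yolk sac CD45+ difference was 4.02 without Y+ C1 and 3.42 with normexp. The spread, estimated over all groups, held 1 yolk sac CD45+ control array at −6.20, not well above background, beside its replicate at −2.09. Embryo CD45− cells passed at adjusted p = 0.000973 with normexp and 0.0272 on the slide alone, and embryo CD45+ cells at adjusted p = 0.00139 with normexp and 0.0122 on the slide alone. The Etv2 probe lay on chromosome 7 at 31418776 to 31418835 (mm9 coordinates of the files) and had the sequence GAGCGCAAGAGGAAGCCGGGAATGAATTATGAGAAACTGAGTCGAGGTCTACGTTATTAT. A second Etv2 probe differed by 2.92 in embryo CD45−, 3.00 in embryo CD45+, 6.75 in yolk sac CD45− and 5.54 in yolk sac CD45+ cells. Whether these probes read the transgene, the endogenous transcript or both is not given in the sources used here, nor is their exon position.

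Of the genes of the sorting markers, Ptprc was higher in CD45+ control cells, as its gate asks, while Cdh5 was lower there, at −5.98 ± 0.21 (adjusted p = 5.51e-09), although the labels call both gates VE-cadherin-positive. Cdh5 (probe on chromosome 8, 106668159 to 106668218) stood at 5.78 ± 0.14 (SD) in embryo CD45− and −0.17 ± 0.71 in embryo CD45+ control cells, and at 5.75 ± 0.34 and −0.26 ± 0.26 in the yolk sac. Ptprc (chromosome 1, 139961083 to 139961142) stood at 3.22 ± 0.48 in embryo and 3.34 ± 0.10 in yolk sac CD45+ control cells, and was not well above background on any CD45− control array. Tek (chromosome 4, 94540624 to 94540683) stood at 3.48 ± 0.27 and 4.22 ± 0.21 in embryo and yolk sac CD45− control cells and at −3.16 ± 0.08 and −2.45 ± 0.69 in the CD45+ control cells. In Tie-2-Etv2 CD45+ cells Tek stood at 0.34 ± 0.30 in the embryo and 2.58 ± 0.09 in the yolk sac.

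**Figure D1:**
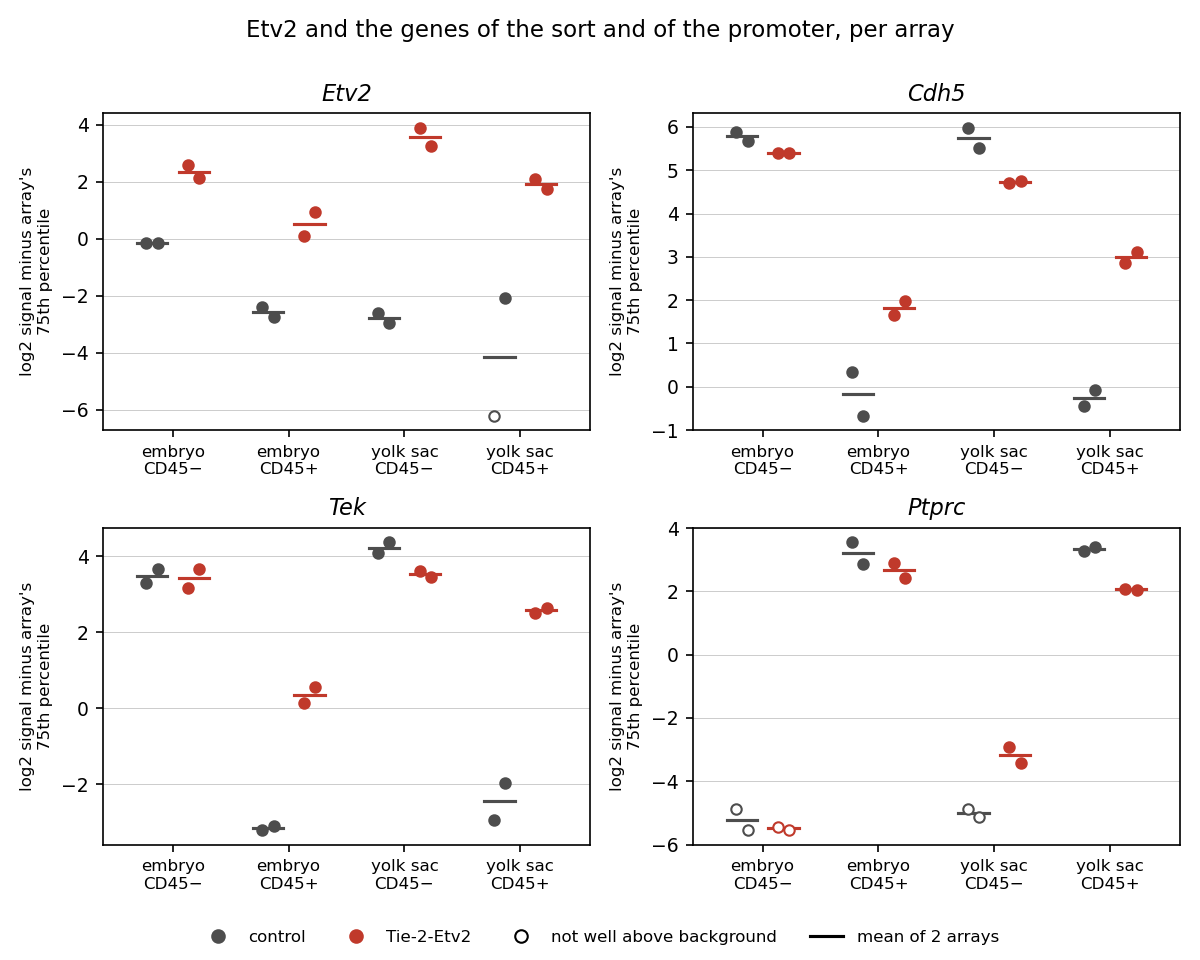
Level of Etv2, Cdh5, Tek and Ptprc on each of the 16 arrays (log2 signal relative to the 75th percentile of the array), by group; points are arrays, open points were not well above background, and bars are the mean of the 2 arrays of a group. Tek stood at −3.16 in embryo CD45+ control cells and at 0.34 in embryo CD45+ Tie-2-Etv2 cells.

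The gates were compared in control cells to show what they separated without the transgene, as the mean over both tissues of CD45+ minus CD45− cells (4 arrays against 4). CD45+ control cells carried macrophage and leukocyte transcripts, and CD45− control cells endothelial ones. C1qc, a complement component of macrophages, was at least 4582-fold and Cx3cr1, the fractalkine receptor, at least 4826-fold higher in CD45+ cells (adjusted p = 2.37e-09). F13a1, a coagulation factor subunit made by macrophages, was higher by 11.28 ± 0.20, and Rac2, a GTPase of blood cells, by 9.35 ± 0.18 (adjusted p = 1.20e-10). Emcn (endomucin) differed by −7.61 ± 0.18 (adjusted p = 2.81e-10) and Plvap by −7.54 ± 0.18, both lower in CD45+ cells. Of 24578 genes, 12178 differed, 6993 higher and 5185 lower in CD45+ cells (5912 and 6197 with quantile normalization, 5155 and 6801 with detected-probe scaling, 6001 and 3292 with the strict filter, 4201 and 3681 on embryo arrays).

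Of 31 pan-leukocyte genes 31 were higher in CD45+ control cells and 0 lower (31 and 0 adjusted over the list alone). Their median was 6.16 (adjusted p = 3.46e-22, estimated-correlation p = 0.0201). Of 40 macrophage genes 37 were higher and 1 lower (37 and 1 so adjusted). Their median was 7.50 (adjusted p = 9.33e-21, estimated-correlation p = 0.0123; 3.74 with the strict filter). Among 43 pan-endothelial genes 1 was higher and 41 lower (1 and 41 so adjusted). Their median was −5.98 (adjusted p = 6.51e-27, estimated-correlation p = 0.0201). Among 20 vascular basement membrane genes 0 were higher and 20 lower (0 and 20 so adjusted). Their median was −5.32 (adjusted p = 2.35e-16, estimated-correlation p = 0.0252), with Col4a2, a collagen IV chain, at −6.77 ± 0.21. Of 28 interferon response genes 26 were higher and 0 lower (26 and 1 so adjusted). Their median was 3.20 (adjusted p = 1.33e-06, estimated-correlation p = 0.344), with Oas2 at 7.98 ± 0.47. On each slide alone the pan-endothelial median was −5.89 in the embryo and −6.01 in the yolk sac, the pan-leukocyte median 6.52 and 5.98, the macrophage median 7.70 and 7.44, the basement membrane median −5.53 and −5.25, and the interferon median 4.21 and 2.11. Camera also called lists higher (granulocyte and mast cell, cell cycle) and lower (early Etv2-dependent blood and endothelial regulators, arterial endothelial, venous and capillary endothelial, lymphatic endothelial, angiogenic sprouting, Notch pathway, blood-brain-barrier endothelial, mesenchymal and mural cell, endothelial-to-mesenchymal transition, yolk sac endoderm and liver, neural, cardiac and skeletal muscle), at an estimated-correlation p of 0.0123 to 0.707, with calls lost under at least 1 alternative for some of them (blood-brain-barrier endothelial, granulocyte and mast cell, yolk sac endoderm and liver, neural). Gate and slide column cannot be told apart.

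In CD45− cells of the embryo, genes of leukocytes and megakaryocytes rose in Tie-2-Etv2 samples, while 0 pan-endothelial genes passed the limma test (1 higher and 1 lower at an unadjusted p under 0.05). Rac2 rose by 6.10 ± 0.26 (68.6-fold, adjusted p = 1.10e-06), Vav1, a guanine nucleotide exchange factor of blood cells, by 4.97 ± 0.23 (adjusted p = 1.38e-06), and Fermt3, the integrin activator kindlin-3, by 4.87 ± 0.18 (adjusted p = 7.70e-07). Lyz2, a lysozyme of myeloid cells, was at least 24.3-fold higher (adjusted p = 1.10e-06; 2.43 on the log2 scale with normexp), having not been well above background in controls. The potassium channel gene Kcnj5 rose by 6.54 ± 0.46 and the tubulin gene Tuba8 by 7.31 ± 0.53. In all, 317 of 24578 genes passed, 308 higher and 9 lower in Tie-2-Etv2 cells (327 and 14 with quantile normalization, 233 and 5 with normexp, 273 and 16 without a filter on dim probes, 174 and 2 with the strict filter, 325 and 3 with a trended robust prior, 134 and 0 by limma on the 4 arrays alone with 1503 at an unadjusted p under 0.05, 229 and 4 on the slide alone, 330 and 84 without E− C2, 265 and 15 without E− Tg1).

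In embryo CD45− cells, of 31 pan-leukocyte genes 21 rose and 0 fell (25 and 0 adjusted over the list alone). Their median was 2.56 (adjusted p = 5.56e-62, estimated-correlation p = 0.00363; 1.18 with normexp). Was, mutated in Wiskott-Aldrich syndrome, rose by 4.64 ± 0.21 and Plek by 5.37 ± 0.27, whereas Ptprc was not well above background in either genotype. Of 32 megakaryocyte and platelet genes 15 rose and 0 fell (22 and 0 so adjusted). Their median was 2.23 (adjusted p = 3.89e-38, estimated-correlation p = 0.0132). They included Itga2b, the integrin subunit CD41, at 4.33 ± 0.47, Rgs18 at 5.24 ± 0.25 (2.81 with normexp) and P2rx1, a platelet ATP receptor, at 4.13 ± 0.23. Among 36 hemogenic endothelium and stem cell genes 8 rose and 0 fell (11 and 0 so adjusted). Their median was 0.44 (adjusted p = 1.63e-08, estimated-correlation p = 0.243; 0.26 with the probe mean), with Gfi1b, a transcriptional repressor of blood cells, at 3.94 ± 0.40. Of 26 granulocyte and mast cell genes 1 rose and 0 fell (7 and 0 so adjusted). Their median was 0.32 (adjusted p = 0.00106, estimated-correlation p = 0.436; 0.21 with quantile normalization, 0.11 without a filter on dim probes, 0.50 without E− C1 and 0.0279 without E− Tg2, lost at adjusted p = 0.909 at median −0.19 with the strict filter and 0.0863 at median 0.067 without E− C2). Mpo, myeloperoxidase, rose by 5.00 ± 0.53 (adjusted p = 0.000576). Of 36 erythroid genes 1 rose and 0 fell (4 and 0 so adjusted). Their median was 0.59 (adjusted p = 2.09e-08, estimated-correlation p = 0.267; 0.89 without E− C2 and 1.03 or 0.37 without E− Tg1 or Tg2); Gata1, the erythroid and megakaryocyte transcription factor, rose by 4.10 ± 0.45, while the embryonic globin gene Hbb-bh1 differed by 1.69 ± 0.83 (adjusted p = 0.784).

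By camera, pan-endothelial genes shifted lower as a list in embryo CD45− Tie-2-Etv2 cells. Of 43 genes 0 rose and 0 fell (0 and 0 adjusted over the list alone). Their median was −0.34 (adjusted p = 0.00212, estimated-correlation p = 0.465, fry's adjusted p = 0.395). Fry called 2 lists higher and 0 lower in these cells. Cdh5 differed by −0.38 ± 0.30 (adjusted p = 0.977), Pecam1, the adhesion molecule CD31, by −0.56 ± 0.23 (adjusted p = 0.627) and Emcn by −0.29 ± 0.25 (adjusted p = 0.983). Macrophage genes did not shift as a list (median −0.22, mean 0.24, adjusted p = 0.964): 5 of 40 rose, Lyz2 among them, and 1 fell (5 and 2 so adjusted), with C1qc at least 2.06-fold lower (adjusted p = 0.00148). The C1qc call was lost at adjusted p = 0.964 at −0.17 with normexp and 0.0674 on the 4 arrays alone. Camera also called arterial endothelial −0.37 (0.267, lost at 0.0655 without E− C2); lymphatic endothelial −0.65 (0.267, −1.01 without E− C2, lost at 0.197 with the strict filter and 0.106 at median −0.38 without E− C1); angiogenic sprouting −0.36 (0.292, −0.55 with the strict filter and −0.57 without E− C2, lost at 0.101 at median −0.19 without E− C1); vascular basement membrane −0.37 (0.415, lost at 0.0817 without E− C2); blood-brain-barrier endothelial −0.42 (0.267, lost at 0.0635 at median −0.21 with the strict filter, 0.0838 without E− C2 and 0.0787 at median −0.23 without E− Tg2); endothelial-to-mesenchymal transition −0.42 (0.356, lost at 0.0861 without E− C2 and 0.265 at median −0.0899 without E− Tg2); yolk sac endoderm and liver −0.67 (0.691, −0.36 with normexp, −1.27 without E− C2 and −1.11 without E− Tg1, lost at 0.101 without E− C1); cell cycle 0.22 (0.356, 0.33 without E− C2, lost at 0.209 at median 0.094 without E− C1).

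In CD45− cells of the yolk sac, genes that rose included blood cell genes, and genes that fell included endothelial, basement membrane and mural cell genes. Rac2 rose by 9.17 ± 0.26 (575-fold, adjusted p = 1.24e-08), Fermt3 by 7.37 ± 0.18 (adjusted p = 9.15e-09), Mpo by 9.74 ± 0.53 (adjusted p = 9.93e-07) and F13a1 by 8.35 ± 0.29 (adjusted p = 3.84e-08). Lilrb4a, a leukocyte receptor gene, was at least 2295-fold higher and Rgs18 at least 352-fold higher, having not been well above background in controls (8.00 and 5.32 on the log2 scale with normexp). Emcn differed by −3.60 ± 0.25 (adjusted p = 4.88e-06) and Col4a2 by −3.68 ± 0.29 (adjusted p = 1.03e-05). Of 24578 genes 10309 passed, 6428 higher and 3881 lower (4066 and 5618 with detected-probe scaling, 4270 and 2778 without Y− C2, 3933 and 2676 without Y− Tg1).

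In yolk sac CD45− cells, of 31 pan-leukocyte genes 28 rose and 1 fell (28 and 1 adjusted over the list alone). Their median was 4.47 (adjusted p = 6.72e-18, estimated-correlation p = 0.0599). Ptprc itself was at least 3.33-fold higher (adjusted p = 0.000801), a call lost at adjusted p = 0.249 at 0.38 with normexp, and Cd52 at least 308-fold higher (adjusted p = 6.99e-08; 5.26 on the log2 scale with normexp). Of 32 megakaryocyte and platelet genes 24 rose and 3 fell (25 and 3 so adjusted). Their median was 4.30 (adjusted p = 1.12e-09, estimated-correlation p = 0.10), with Bin2 at 7.80 ± 0.19 and P2rx1 at 6.34 ± 0.23. Among 36 hemogenic endothelium and stem cell genes 18 rose and 8 fell (20 and 9 so adjusted). Their median was 1.14 (adjusted p = 0.0491, estimated-correlation p = 0.483; lost at adjusted p = 0.0929 with the strict filter, 0.0638 on the 4 arrays alone and 0.0549 without Y− Tg2). Runx1, the regulator of blood emergence from endothelium, rose by 4.62 ± 0.67, Myb by 5.32 ± 0.41 and Gfi1b by 6.08 ± 0.40, and Spi1 (PU.1) was at least 30.2-fold higher (adjusted p = 2.42e-06; 2.14 on the log2 scale with normexp). Macrophage genes did not shift as a list (median 0.29, adjusted p = 0.222; adjusted p = 0.0494 with detected-probe scaling), with 13 of 40 higher and 8 lower (13 and 8 so adjusted).

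Of 43 pan-endothelial genes in these cells 1 rose and 32 fell (2 and 32 adjusted over the list alone). Their median was −1.99 (adjusted p = 7.12e-12, estimated-correlation p = 0.10). Calcrl, the adrenomedullin receptor, fell by 2.96, Plvap fell by 2.75 and Nos3, endothelial nitric oxide synthase, fell by 3.29 on the log2 scale. Cdh5 differed by −1.01 ± 0.30 (adjusted p = 0.0214; lost at adjusted p = 0.144 without Y− C1 and 0.0909 or 0.0662 without Y− Tg1 or Tg2), and the VEGF receptor gene Kdr by −1.04 ± 0.26 (adjusted p = 0.0093; lost at adjusted p = 0.0542 without Y− C1 and 0.0642 without Y− Tg2). Tek differed by −0.69 ± 0.31 (adjusted p = 0.0979) and passed at adjusted p = 0.0227 with quantile normalization, 0.0243 with normexp, 0.0395 with detected-probe scaling and 0.0485 on the 4 arrays alone. Among 23 arterial endothelial genes 0 rose and 19 fell (0 and 19 so adjusted). Their median was −2.63 (adjusted p = 1.60e-10, estimated-correlation p = 0.0599), with Efnb2 at −2.92 ± 0.34. Of 20 vascular basement membrane genes 0 rose and 17 fell (0 and 17 so adjusted). Their median was −2.91 (adjusted p = 5.74e-11, estimated-correlation p = 0.10), with Col4a1 at −3.50 ± 0.33. Of 13 lymphatic genes 1 rose and 7 fell (1 and 8 so adjusted). Their median was −1.71 (adjusted p = 0.000956, estimated-correlation p = 0.10; −1.12 with normexp and −0.85 or −2.56 without Y− Tg1 or Tg2).

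Markers of other cell types moved beside these groups in yolk sac CD45− cells. Of 32 mesenchymal and mural cell genes 0 rose and 18 fell (0 and 20 adjusted over the list alone). Their median was −2.12 (adjusted p = 3.80e-09, estimated-correlation p = 0.154; −1.12 with normexp and −1.34 with the strict filter), with Notch3 at −3.80 ± 0.53 and Acta2, smooth muscle actin, at −2.90 ± 0.44. Of 23 epithelial genes 0 rose and 12 fell (0 and 15 so adjusted). Their median was −2.20 (adjusted p = 2.39e-05, estimated-correlation p = 0.256; −0.98 with normexp and −0.93 without Y− Tg1), with the membrane protease gene St14 at −2.83 ± 0.38. Of 31 yolk sac endoderm and liver genes 0 rose and 5 fell (0 and 5 so adjusted). Their median was −1.81 (adjusted p = 9.95e-06, estimated-correlation p = 0.455; −0.41 or −3.40 without Y− Tg1 or Tg2). Of 31 neural genes 0 rose and 12 fell (0 and 12 so adjusted). Their median was −0.47 (adjusted p = 8.79e-05, estimated-correlation p = 0.376; −0.31 with normexp, −0.78 with detected-probe scaling, −0.85 with the probe mean, −0.75 without Y− C2 and −0.79 or −0.80 without Y− Tg1 or Tg2). Of 27 cardiac and skeletal muscle genes 3 rose and 11 fell (3 and 11 so adjusted). Their median was −0.67 (adjusted p = 0.0132, estimated-correlation p = 0.10; −0.24 with normexp and −1.03 without Y− C2, lost at adjusted p = 0.0596 with quantile normalization and 0.0653 with detected-probe scaling). The trefoil factor gene Tff1 fell by 9.21, the gastrokine gene Gkn2 fell by 7.95 and Gsta1, a glutathione transferase, fell by 7.05 on the log2 scale. Of 40 cell cycle genes 31 rose and 0 fell (34 and 0 so adjusted). Their median was 0.94 (adjusted p = 2.95e-09, estimated-correlation p = 0.154; 0.62 with quantile normalization and 0.62 with detected-probe scaling), with Mcm5, a replication helicase subunit, at 1.38 ± 0.16. Of 27 dissociation stress genes, which cell isolation is known to induce, 2 rose and 13 fell (2 and 14 so adjusted). Their median was −1.13 (adjusted p = 0.000221, estimated-correlation p = 0.313), with Fos at −3.15 ± 0.37. Camera also called early Etv2-dependent blood and endothelial regulators −1.01 (0.20, −0.31 with the strict filter); venous and capillary endothelial −1.57 (0.0802); angiogenic sprouting −1.18 (0.10); Notch pathway −1.20 (0.0599, −0.78 with normexp and −0.31 with the strict filter); endothelial-to-mesenchymal transition −1.60 (0.136, −0.79 with normexp); interferon response −1.33 (0.455). With detected-probe scaling the median of all genes was −0.14 against 0.18.

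In CD45+ cells of the embryo, genes that rose in Tie-2-Etv2 samples included some of the endothelial, megakaryocyte and granulocyte lists. Tek rose by 3.50 ± 0.31 (11.3-fold, adjusted p = 0.000225), Sox18, an endothelial transcription factor, by 5.09 ± 0.65 (adjusted p = 0.00227) and Clec1b, the platelet receptor CLEC-2, by 4.36 ± 0.28 (adjusted p = 4.44e-05). Retnlg, a resistin-like gene of neutrophils, was at least 59.6-fold higher (adjusted p = 2.07e-05; 3.58 on the log2 scale with normexp), and Kcnj5 rose by 6.53 ± 0.46. Ptprc differed by −0.55 ± 0.30 (adjusted p = 0.418). With normexp the difference was 2.27 for Tek, 3.14 for Sox18 and 3.76 for Kcnj5. Of 24578 genes 744 passed, 563 higher and 181 lower (657 and 469 with normexp, 439 and 98 without a filter on dim probes, 377 and 203 with the strict filter, 723 and 342 with a trended robust prior, 354 and 59 on the slide alone, 533 and 398 without E+ C2, 262 and 22 without E+ Tg2).

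Of 43 pan-endothelial genes in embryo CD45+ cells 16 rose and 0 fell (28 and 2 adjusted over the list alone). Their median was 1.19 (adjusted p = 1.36e-16, estimated-correlation p = 0.16). Egfl7 rose by 1.88 ± 0.19. Cdh5 rose by 1.98 ± 0.30 (adjusted p = 0.00599; lost at adjusted p = 0.0525 on the slide alone and 0.0658 without E+ Tg2). Kdr read −0.03 ± 0.26 on its brightest probe and 2.00 on another probe, and passed as the mean over its probes (0.99, adjusted p = 0.0131). Of 36 hemogenic endothelium and stem cell genes 12 rose and 0 fell (17 and 0 so adjusted). Their median was 0.68 (adjusted p = 4.14e-11, estimated-correlation p = 0.16; 1.17 with the strict filter), with Gata2 at 3.45 ± 0.48, while Runx1 read −0.47 ± 0.67 (adjusted p = 0.85). Of 26 granulocyte and mast cell genes 9 rose and 0 fell (16 and 1 so adjusted). Their median was 3.14 (adjusted p = 1.43e-13, estimated-correlation p = 0.181). Of 32 megakaryocyte and platelet genes 15 rose and 1 fell (20 and 2 so adjusted). Their median was 1.57 (adjusted p = 1.46e-09, estimated-correlation p = 0.226), with Itga2b at 4.78 ± 0.47.

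Macrophage genes shifted lower in embryo CD45+ Tie-2-Etv2 cells: of 40 genes 2 rose and 2 fell (3 and 9 adjusted over the list alone). Their median was −0.86 (adjusted p = 4.03e-05, estimated-correlation p = 0.232). Adgre1, the macrophage marker F4/80, differed by −1.45 ± 0.26 (adjusted p = 0.0148; lost at adjusted p = 0.0733 on the slide alone, 0.0815 without E+ C1 and 0.146 without E+ Tg2), while Lyz2 rose by 1.88 ± 0.29 (adjusted p = 0.0065; lost at adjusted p = 0.0735 without E+ Tg2). Clec4f, a Kupffer cell receptor gene, was at least 7.65-fold lower (adjusted p = 0.00988; lost at adjusted p = 0.102 at −1.19 with normexp, 0.0897 on the slide alone and 0.0987 without E+ Tg2). Of 28 interferon response genes 0 rose and 2 fell (0 and 17 so adjusted). Their median was −1.80 (adjusted p = 7.50e-12, estimated-correlation p = 0.296; −0.90 without E+ C1), with Oasl2 at −2.30 ± 0.41 (adjusted p = 0.0143; lost at adjusted p = 0.0854 without E+ C1 and 0.061 or 0.0932 without E+ Tg1 or Tg2). Of 27 dissociation stress genes 0 rose and 0 fell (0 and 0 so adjusted). Their median was −0.70 (adjusted p = 0.000151, estimated-correlation p = 0.528), with 0 higher and 8 lower by limma at an unadjusted p under 0.05. Camera also called early Etv2-dependent blood and endothelial regulators 0.52 (0.232, 0.24 with normexp and 0.91 without E+ C2, lost at 0.232 at median 0.16 without E+ C1); venous and capillary endothelial 0.32 (0.16, 0.59 with the strict filter, 0.95 without E+ C2 and 0.74 or 0.53 without E+ Tg1 or Tg2, lost at 0.0518 at median 0.14 with normexp and 0.126 at median −0.16 without E+ C1); cell cycle 0.24 (0.615); hypoxia and glycolysis 0.25 (0.782, 0.57 without E+ C1, lost at 0.469 at median −0.037 without E+ C2). On the 4 arrays of the comparison alone limma called 0 genes, with 2892 at an unadjusted p under 0.05, so that every gene call of embryo CD45+ cells was lost there, while camera called 12 of 29 lists.

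In CD45+ cells of the yolk sac, genes that rose included endothelial, stem cell and megakaryocyte genes, and genes that fell included macrophage and interferon genes. Tek rose by 5.02 ± 0.31 (32.5-fold, adjusted p = 7.25e-06), Cdh5 by 3.25 ± 0.30 (adjusted p = 4.16e-05), Clec1b by 7.85 ± 0.28 (adjusted p = 6.70e-07) and Itga2b by 7.17 ± 0.47 (adjusted p = 9.25e-06). Adgre1 differed by −4.55 ± 0.26 (adjusted p = 6.01e-06), Csf1r, the macrophage growth factor receptor, by −3.34 ± 0.26 (adjusted p = 1.76e-05) and Ptprc by −1.28 ± 0.30 (adjusted p = 0.0074). Of 24578 genes 8014 passed, 4449 higher and 3565 lower (4017 and 4050 with detected-probe scaling, 2287 and 2223 on the 4 arrays alone, 2793 and 2473 without Y+ Tg1).

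Of 43 pan-endothelial genes in yolk sac CD45+ cells 28 rose and 5 fell (29 and 6 adjusted over the list alone). Their median was 1.46 (adjusted p = 7.05e-07, estimated-correlation p = 0.595), with Pecam1 at 2.58 ± 0.23, Erg, an ETS factor of endothelium, at 4.15 ± 0.58 (1.87 with normexp) and Sox18 at 5.72 ± 0.65. Kdr read −0.20 ± 0.26 on its brightest probe and 3.91 on another (1.85 as the mean over its probes, adjusted p = 4.23e-05), and Runx1 −0.22 ± 0.67 and 0.63. Of 36 hemogenic endothelium and stem cell genes 20 rose and 1 fell (22 and 1 so adjusted). Their median was 1.27 (adjusted p = 3.29e-07, estimated-correlation p = 0.542; 2.93 with the strict filter), with Gata2 at 5.83 ± 0.48. Of 26 granulocyte and mast cell genes 16 rose and 2 fell (16 and 3 so adjusted). Their median was 2.94 (adjusted p = 0.000404, estimated-correlation p = 0.696; lost at adjusted p = 0.35 with the strict filter), with Mpo at 3.68 ± 0.53. Of 32 megakaryocyte and platelet genes 21 rose and 4 fell (22 and 4 so adjusted). Their median was 2.77 (adjusted p = 3.29e-07, estimated-correlation p = 0.595).

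In yolk sac CD45+ cells, of 40 macrophage genes 1 rose and 33 fell (1 and 34 adjusted over the list alone). Their median was −3.41 (adjusted p = 1.84e-15, estimated-correlation p = 0.0766), with C1qc at −4.25 ± 0.33. Of 28 interferon response genes 0 rose and 18 fell (0 and 25 so adjusted). Their median was −2.88 (adjusted p = 4.43e-10, estimated-correlation p = 0.595), with Mx1, an antiviral GTPase gene, at −5.34 ± 0.97. Of 27 dissociation stress genes 2 rose and 15 fell (3 and 17 so adjusted). Their median was −1.26 (adjusted p = 3.22e-05, estimated-correlation p = 0.631). Of 31 yolk sac endoderm and liver genes 0 rose and 1 fell (0 and 1 so adjusted). Their median was −1.29 (adjusted p = 0.00398, estimated-correlation p = 0.87; −2.30 without Y+ C2 and −2.24 without Y+ Tg2, lost at median −0.35 without Y+ C1 and −0.45 without Y+ Tg1). Of 32 mesenchymal and mural cell genes 2 rose and 8 fell (2 and 9 so adjusted). Their median was −1.12 (adjusted p = 0.0098, estimated-correlation p = 0.792; −0.47 with normexp, lost at adjusted p = 0.157 at median −0.60 without Y+ C1). Camera also called early Etv2-dependent blood and endothelial regulators 0.55 (0.696, 0.83 with the strict filter, lost at 0.050 on the 4 arrays alone); endothelial-to-mesenchymal transition −1.28 (0.706, lost at 0.0586 with quantile normalization, 0.336 at median −0.38 with normexp, 0.0746 with detected-probe scaling, 0.0625 without a filter on dim probes, 0.518 at median −0.37 with the strict filter, 0.26 without Y+ C1 and 0.0648 without Y+ Tg1); neural −0.48 (0.792, −0.26 with normexp and −0.18 without Y+ C1, lost at 0.0622 at median −0.18 with the strict filter and 0.0555 at median −0.19 without Y+ Tg2); cell cycle 0.46 (0.696, 0.27 without Y+ C2); hypoxia and glycolysis 0.58 (0.792, 0.37 without Y+ Tg1, lost at 0.0811 at median 0.35 without Y+ C2).

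**Figure D2:**
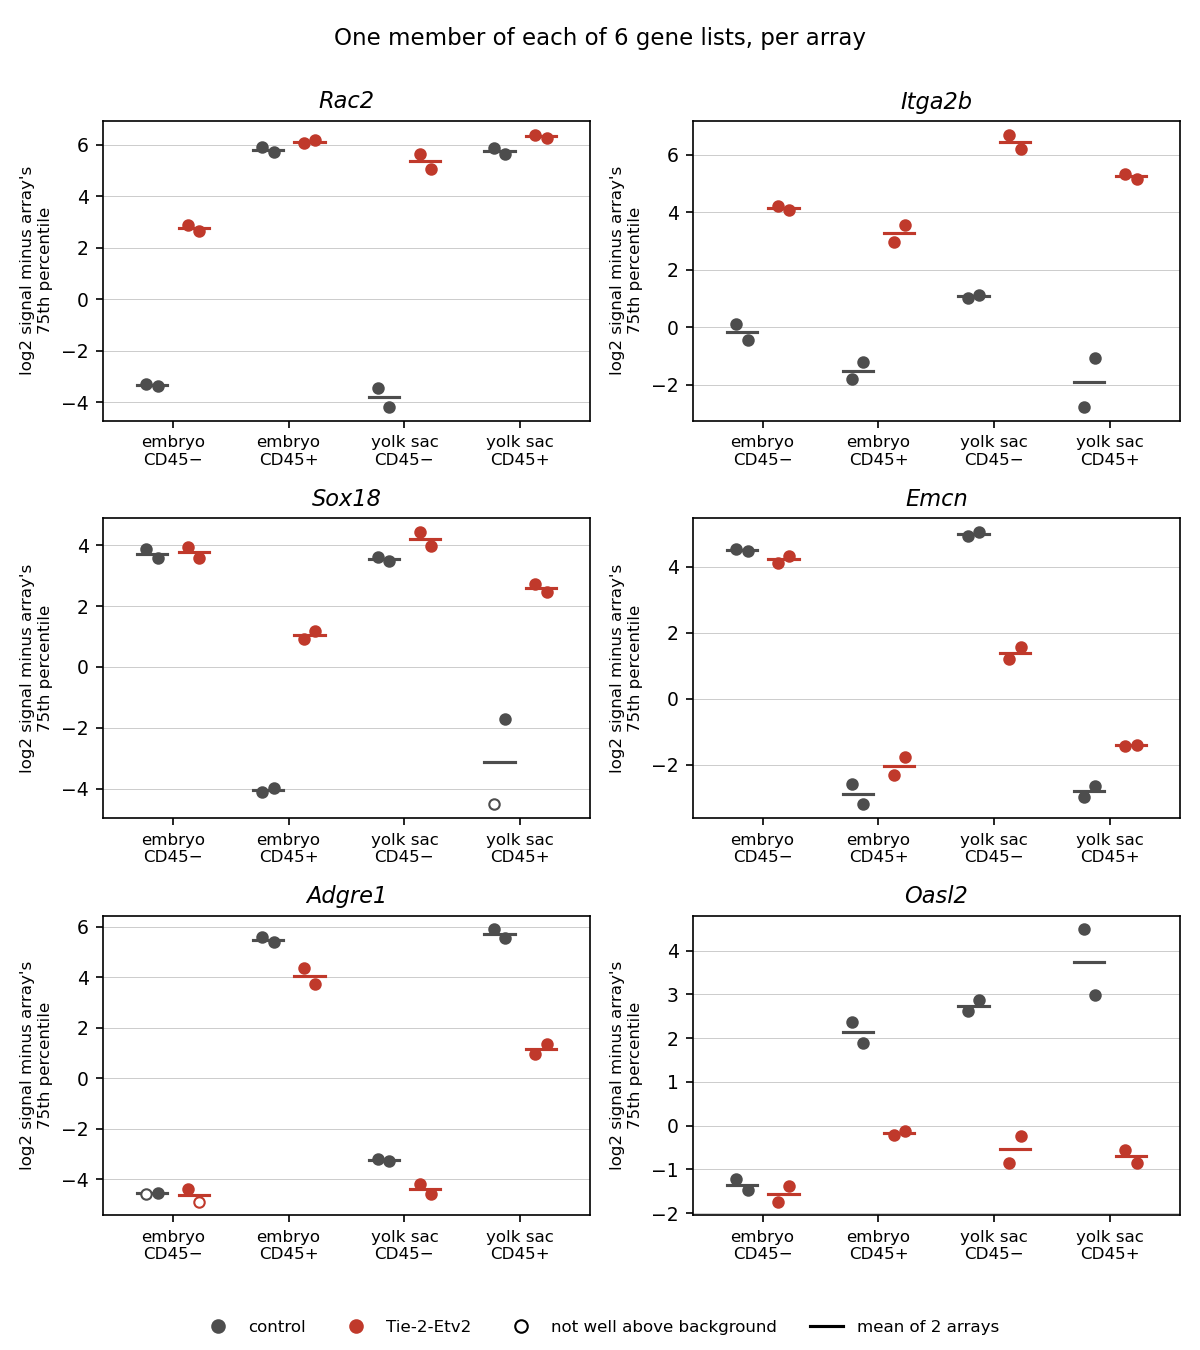
Level of Rac2, Itga2b, Sox18, Emcn, Adgre1 and Oasl2 on each of the 16 arrays (log2 signal relative to the 75th percentile of the array), by group; points are arrays, open points were not well above background, and bars are the mean of the 2 arrays of a group. Rac2 in CD45− cells stood at −3.33 in embryo and −3.81 in yolk sac controls and at 2.77 and 5.36 in Tie-2-Etv2 cells.

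The effects in each gate were set side by side across tissues, which were measured on separate arrays. Across genes, which are not independent, the Tie-2-Etv2 effects of embryo and yolk sac CD45+ cells correlated at r = 0.68. Of the 563 genes that rose in the embryo, 521 also rose in the yolk sac, against 102 by the overlap of independent lists, 148 fell in both against 26.2, and 0 passed in opposite directions. For CD45− cells r was 0.58, and 294 of 308 genes rose in both, against 80.5 by the overlap of independent lists, with 2 passing in opposite directions.

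Averaged over the 4 populations (8 arrays against 8, compared within population), genes that rose included blood and megakaryocyte genes, and genes that fell included interferon genes. Etv2 rose by 4.50 ± 0.48 (adjusted p = 5.13e-05; 2.79 on the embryo arrays alone), Tuba8 by 7.84 ± 0.27 and Itga2b by 5.41 ± 0.24, and Kcnj5 was at least 197-fold higher. Rtp4, an interferon-induced gene, differed by −2.92 ± 0.35 (lost at adjusted p = 0.151 at −1.94 on embryo arrays). Of 24578 genes 11037 passed, 6184 higher and 4853 lower (5141 and 6099 with detected-probe scaling, 421 and 37 on embryo arrays). Of 31 pan-leukocyte genes 26 rose and 0 fell (26 and 1 adjusted over the list alone). Their median was 2.06 (adjusted p = 2.03e-14, estimated-correlation p = 0.314; 1.11 with normexp), with a median of 1.48 on the embryo and 2.66 on the yolk sac arrays alone. Of 28 interferon response genes 0 rose and 23 fell (0 and 23 so adjusted). Their median was −1.57 (adjusted p = 9.27e-09, estimated-correlation p = 0.361), with medians of −1.16 and −2.02. Of 40 cell cycle genes 31 rose and 0 fell (31 and 0 so adjusted). Their median was 0.46 (adjusted p = 9.39e-09, estimated-correlation p = 0.361), with medians of 0.23 and 0.68. Of 27 hypoxia and glycolysis genes 14 rose and 3 fell (18 and 5 so adjusted). Their median was 0.47 (adjusted p = 0.00574, estimated-correlation p = 0.529), with medians of 0.20 and 0.87. Camera also called arterial endothelial −0.78 (−0.17 and −1.31, 0.361, lost at 0.604 on embryo arrays); angiogenic sprouting −0.39 (−0.34 and −0.51, 0.361, lost at 0.358 on embryo arrays); vascular basement membrane −0.91 (−0.02 and −1.62, 0.361, lost at 0.929 on embryo arrays); hemogenic endothelium and stem cell 1.48 (0.71 and 2.00, 0.361, 0.94 with normexp); macrophage −0.997 (−0.61 and −1.31, 0.361); granulocyte and mast cell 2.04 (1.98 and 1.39, 0.361, 1.13 with normexp, lost at 0.457 at median 0.92 with the strict filter); megakaryocyte and platelet 3.42 (2.41 and 4.22, 0.361); mesenchymal and mural cell −0.77 (−0.08 and −1.47, 0.361, −0.49 with normexp, lost at 0.321 on embryo arrays); endothelial-to-mesenchymal transition −0.89 (−0.23 and −1.53, 0.361, −0.35 with normexp, lost at 0.0508 with the strict filter and 0.321 on embryo arrays); yolk sac endoderm and liver −1.08 (−0.52 and −1.58, 0.529, −0.71 without Y− Tg1); neural −0.32 (0.12 and −0.93, 0.529, −0.10 with normexp, −0.19 without a filter on dim probes and −0.56 without E+ C1, lost at 0.993 on embryo arrays, 0.0719 at median −0.20 without E− C2 and 0.0767 at median −0.15 without E+ C2); epithelial −1.07 (−0.60 and −1.65, 0.38, −0.38 with normexp and −0.64 with the strict filter); dissociation stress −0.999 (−0.48 and −1.10, 0.361, −0.66 without E− C1).

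The effect of Tie-2-Etv2 differed between CD45+ and CD45− cells in 3862 of 24578 genes, tested as the mean effect of the CD45+ minus that of the CD45− populations, 1627 higher and 2235 lower (2056 and 1874 with detected-probe scaling, 74 and 92 on embryo arrays). Endothelial genes had the higher effect in CD45+ cells: Tek by 4.63 ± 0.31 (adjusted p = 8.39e-06), Sox18 by 5.06 ± 0.65 (adjusted p = 0.000579; 3.28 with normexp) and Pecam1 by 3.19 ± 0.23 (adjusted p = 1.40e-05; lost at adjusted p = 0.165 at 1.84 on embryo arrays). Leukocyte genes had the lower effect there: F13a1 differed by −8.31 ± 0.29 (−5.12 on the embryo arrays alone), Rac2 by −7.19 ± 0.26 and Plek by −7.33 ± 0.27 (adjusted p = 1.36e-07, 1.36e-07 and 1.36e-07). Of 43 pan-endothelial genes 35 differed upward and 0 downward (36 and 1 adjusted over the list alone). Their median was 2.56 (adjusted p = 1.68e-27, estimated-correlation p = 0.0274), with medians of 1.45 on the embryo and 3.62 on the yolk sac arrays alone. Of 31 pan-leukocyte genes 0 differed upward and 26 downward (1 and 27 so adjusted). Their median was −3.57 (adjusted p = 1.39e-28, estimated-correlation p = 0.0173; −1.91 with normexp and −2.24 with the strict filter), with medians of −2.33 and −4.61.

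Between yolk sac and embryo the effect differed in 4906 genes, 2998 higher and 1908 lower in the yolk sac (2119 and 2098 with quantile normalization, 1462 and 2720 with detected-probe scaling, 1936 and 1379 without a filter on dim probes, 1971 and 1318 without E− Tg1, 1847 and 1441 without E− Tg2, 1682 and 1269 without E+ Tg1, 1958 and 1306 without Y− C1, 1834 and 1292 without Y− C2, 1721 and 1335 without Y− Tg1, 1705 and 1329 without Y+ Tg1). Tissue and slide cannot be told apart. The yolk sac had the larger effect on the megakaryocyte genes Clec1b by 2.96 ± 0.28 and P2rx1 by 2.18 ± 0.23, and the lower effect on the matrix genes Col4a1 by −2.32 ± 0.33 and Lama1, a laminin chain, by −3.82 ± 0.52. Of 32 megakaryocyte and platelet genes 17 differed upward and 0 downward (20 and 1 adjusted over the list alone). Their median was 1.73 (adjusted p = 2.73e-06, estimated-correlation p = 0.318). Of 20 vascular basement membrane genes 0 differed upward and 10 downward (1 and 13 so adjusted). Their median was −1.52 (adjusted p = 7.47e-08, estimated-correlation p = 0.318). Etv2 itself differed by 3.43 ± 0.96 (adjusted p = 0.0318; 2.08 with normexp). The call was lost at adjusted p = 0.056 with quantile normalization, 0.0518 with detected-probe scaling and 0.0531 without a filter on dim probes. It was also lost without E− C1, C2, Tg1 or Tg2, E+ C1 or Tg1, Y− C1, C2 or Tg1, or Y+ Tg1 or Tg2.

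**Figure D3:**
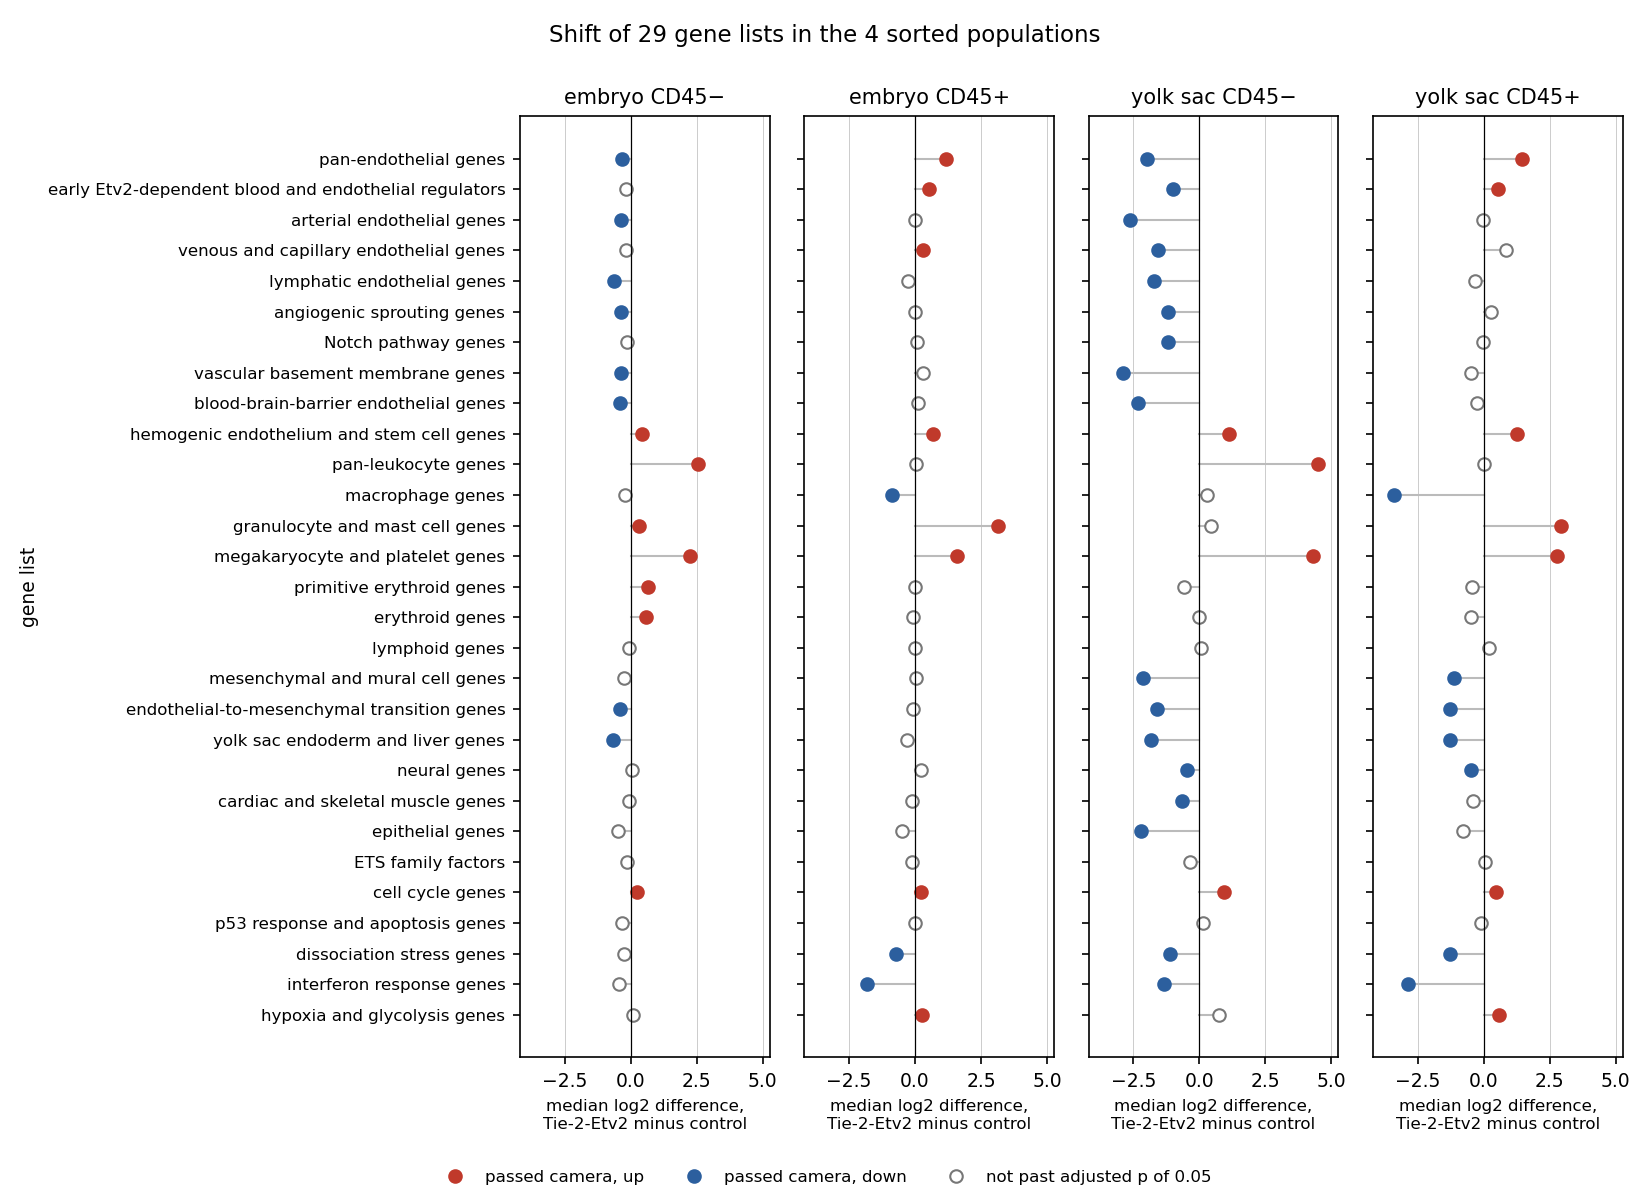
Median log2 difference, Tie-2-Etv2 minus control, of the 29 gene lists in the 4 populations; filled points passed the camera test at an adjusted p under 0.05. Pan-leukocyte genes had medians of 2.56 and 4.47 in embryo and yolk sac CD45− cells and 0.03 and 0.02 in CD45+ cells.

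Control cells of both tissues were compared within each gate. In CD45− cells, genes higher in the yolk sac included endoderm and epithelial genes, and lower ones neural genes. The calcium-binding protein gene S100g was at least 587-fold higher (adjusted p = 0.000181; 6.53 on the log2 scale with normexp) and Apoa4, an apolipoprotein gene, at least 152-fold higher (adjusted p = 0.000351; 4.58 on the log2 scale with normexp), while Fabp7, a radial glia gene, differed by −5.50 ± 0.52 (adjusted p = 0.000202). Of 24578 genes 2842 differed, 1341 higher and 1501 lower (1701 and 1502 with quantile normalization, 1514 and 1442 with normexp, 1601 and 1206 with detected-probe scaling, 1070 and 967 without a filter on dim probes, 784 and 688 without E− C1, 562 and 455 without Y− C1, 519 and 356 without Y− C2). Etv2 differed by −2.64 ± 0.96 (adjusted p = 0.106) and passed at adjusted p = 0.0036 with normexp. Of 31 yolk sac endoderm and liver genes 18 were higher and 0 lower (25 and 0 adjusted over the list alone). Their median was 3.20 (adjusted p = 3.48e-15, estimated-correlation p = 0.445). Of 23 epithelial genes 13 were higher and 0 lower (15 and 0 so adjusted). Their median was 2.96 (adjusted p = 1.74e-10, estimated-correlation p = 0.445; 1.54 with normexp). Of 28 interferon response genes 12 were higher and 0 lower (17 and 0 so adjusted). Their median was 1.93 (adjusted p = 2.00e-12, estimated-correlation p = 0.445). With normexp the difference was −3.15 for Fabp7. Of 31 neural genes 0 were higher and 14 lower (1 and 19 so adjusted). Their median was −1.94 (adjusted p = 7.31e-09, estimated-correlation p = 0.445; −0.82 with normexp, lost at adjusted p = 0.0723 at median −0.75 with the strict filter). Camera also called lists higher (pan-endothelial, arterial endothelial, vascular basement membrane, hemogenic endothelium and stem cell, erythroid, mesenchymal and mural cell, dissociation stress) and lower (blood-brain-barrier endothelial), at an estimated-correlation p of 0.445 to 0.685, with calls lost under at least 1 alternative for some of them (blood-brain-barrier endothelial, hemogenic endothelium and stem cell, mesenchymal and mural cell, dissociation stress).

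In CD45+ control cells the tissues differed in 422 of 24578 genes, 151 higher and 271 lower in the yolk sac (41 and 86 with normexp, 78 and 146 without a filter on dim probes, 43 and 97 with the strict filter, 82 and 377 without E+ C1, 127 and 422 without E+ C2, 111 and 159 without Y+ C1, 467 and 406 without Y+ C2). S100g was at least 204-fold higher (adjusted p = 0.0027; 5.36 on the log2 scale with normexp). Afp, alpha-fetoprotein, was higher by 5.28 ± 0.85 (adjusted p = 0.0163; lost at adjusted p = 0.0782 without Y+ C1). The neural gene Tubb3 differed by −4.92 ± 0.71 (adjusted p = 0.0104; −3.04 with normexp) and Fabp7 was at least 33.4-fold lower (adjusted p = 0.00167; −2.74 on the log2 scale with normexp). Of 31 yolk sac endoderm and liver genes 10 were higher and 0 lower (23 and 0 adjusted over the list alone). Their median was 3.88 (adjusted p = 1.82e-22, estimated-correlation p = 0.383). Fry called 0 lists higher and 2 lower here. Of 31 neural genes 0 were higher and 13 lower (0 and 21 so adjusted). Their median was −2.63 (adjusted p = 8.43e-21, estimated-correlation p = 0.244; −0.97 with normexp, −0.77 with the strict filter and −4.05 without E+ C1). Of 27 cardiac and skeletal muscle genes 0 were higher and 3 lower (0 and 6 so adjusted). Their median was −0.73 (adjusted p = 0.000105, estimated-correlation p = 0.0494; −0.0755 with normexp). Camera also called lists higher (vascular basement membrane, epithelial, interferon response) and lower (early Etv2-dependent blood and endothelial regulators, blood-brain-barrier endothelial), at an estimated-correlation p of 0.443 to 0.872, with calls lost under at least 1 alternative for each of them.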

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

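The tests of admixed cells and of changed cell shares were chosen only after the results were seen, whereas the splits of the samples and the tests of differences between effects were planned.

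The Tie-2-Etv2 effect differed between CD45+ and CD45− cells, by the test of the difference itself, in 3862 genes. 4 of 100 drawn splits of the arrays into control and transgenic called as many. Those besides the real one parted 2 to 4 populations by genotype, turned 1 or 2, and so carry the genotype effect into this contrast. The tally thus cannot decide on a random grouping. The highest other called 7390 (real 3862). Lists that passed camera also with an estimated correlation were, as CD45+ minus CD45− effect, pan-endothelial 2.56 (1.45 and 3.62, 0.0274); arterial endothelial 1.52 (0.33 and 2.05, 0.0288); venous and capillary endothelial 1.28 (0.76 and 1.40, 0.0173, 0.83 with normexp); lymphatic endothelial 1.73 (0.43 and 2.90, 0.0424); Notch pathway 0.70 (0.42 and 1.11, 0.0173); pan-leukocyte −3.57 (−2.33 and −4.61, 0.0173, −1.91 with normexp and −2.24 with the strict filter); macrophage −2.01 (−0.63 and −3.52, 0.0173). The other lists past camera were early Etv2-dependent blood and endothelial regulators 1.17 (0.64 and 1.87, 0.051, 0.68 with the strict filter); angiogenic sprouting 0.88 (0.35 and 1.32, 0.157); vascular basement membrane 1.45 (0.60 and 2.45, 0.0624); blood-brain-barrier endothelial 1.17 (0.39 and 1.95, 0.0578, 0.56 with normexp and 0.53 with the strict filter); hemogenic endothelium and stem cell 0.46 (0.33 and 0.40, 0.503, 0.70 without Y+ C2, lost at 0.129 with quantile normalization, 0.117 with detected-probe scaling, 0.0575 with the probe mean, 0.066 on yolk sac arrays, 0.098 without E− C2, 0.0572 without E+ C1 and 0.11 at median 0.23 without Y+ C1); granulocyte and mast cell 0.68 (0.51 and 0.99, 0.503, 1.97 with normexp, 0.45 without E+ C1, 0.38 or 1.23 without Y+ C1 or C2 and 0.22 or 1.14 without Y+ Tg1 or Tg2, lost at 0.0622 at median 0.26 with the strict filter); megakaryocyte and platelet −0.91 (−0.91 and −0.62, 0.454, −0.55 without Y+ C2, lost at 0.0896 at median −0.32 with the strict filter and 0.0969 on yolk sac arrays); mesenchymal and mural cell 0.59 (0.12 and 1.21, 0.503, 0.15 with normexp, 0.35 with the strict filter, 1.05 or 0.17 without E− Tg1 or Tg2, 0.38 without E+ C1 and 0.30 without Y+ C2, lost at 0.503 on embryo arrays); endothelial-to-mesenchymal transition 0.61 (0.42 and 0.73, 0.33, 0.39 without E− Tg2); epithelial 0.29 (0.27 and 0.85, 0.506, 0.15 with normexp, 0.46 with the strict filter, 0.46 without E− C2, 0.53 without E− Tg2, 0.46 without E+ C1, 0.70 without Y− Tg2 and 0.77 without Y+ C1, lost at 0.0611 with quantile normalization, 0.0712 with detected-probe scaling, 0.753 on embryo arrays, 0.0568 at median 0.19 without E+ C2, 0.0906 without Y− C2, 0.171 at median 0.13 without Y− Tg1 and 0.191 at median −0.0222 without Y+ C2); cell cycle −0.24 (−0.01 and −0.47, 0.506, −0.11 with detected-probe scaling, lost at 0.094 at median −0.11 with quantile normalization, 0.837 on embryo arrays and 0.135 without E− C1); interferon response −1.42 (−1.33 and −1.42, 0.487, −0.93 without E+ C1). On the embryo arrays alone the cell cycle genes turned direction by camera, without passing (median −0.00621, adjusted p = 0.837).

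Among single genes the effect was higher in CD45+ cells for Tek 4.63 ± 0.31, Pecam1 3.19 ± 0.23, Ecscr 3.20 ± 0.23, Cd93 3.43 ± 0.26, Cdh5 3.31 ± 0.30, Sox18 5.06 ± 0.65, Slco3a1 5.14 ± 0.67, Shank3 4.88 ± 0.48, Notch4 3.19 ± 0.32 and Pglyrp1 5.52 ± 0.75 (highest adjusted p 0.000802 for Pglyrp1). It was lower there for Fermt3 −5.75 ± 0.18, Rac2 −7.19 ± 0.26, Vav1 −6.39 ± 0.23, Plek −7.33 ± 0.27, F13a1 −8.31 ± 0.29, Pf4 −7.72 ± 0.32 and Sla −7.98 ± 0.45 (highest adjusted p 2.57e-06 for Sla). On the embryo arrays alone Pecam1 (1.84, adjusted p = 0.165), Ecscr (1.67, adjusted p = 0.196), Cd93 (2.39, adjusted p = 0.096), Cdh5 (2.36, adjusted p = 0.155), Slco3a1 (4.14, adjusted p = 0.0942) and Notch4 (1.56, adjusted p = 0.397) did not pass, and F13a1 differed by −5.12. Notch4 differed by 4.82 on the yolk sac arrays alone. With normexp the difference was 3.28 for Sox18, 3.03 for Shank3 and −5.08 for Sla.

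Between yolk sac and embryo the Tie-2-Etv2 effect differed, by the test of the difference itself, in 4906 genes. 5 of 100 drawn splits of the arrays called as many. The 4 others parted 2 to 4 populations by genotype, 3 of them with 2 populations turned, and so carry the genotype effect into this contrast. The tally thus neither excludes a random grouping nor measures how often one calls as many. The highest of the others called 11037, against the real 4906. Tissue and slide coincide here. All lists that passed camera lost the call with an estimated correlation, and were, as yolk sac minus embryo effect, pan-endothelial −0.65 (0.355, −0.37 without Y− Tg1); arterial endothelial −1.32 (0.275); venous and capillary endothelial −1.05 (0.318, −0.69 without E− C1 and −0.44 without Y− Tg1, lost at 0.0569 with detected-probe scaling); lymphatic endothelial −0.79 (0.318, −1.81 with the strict filter and −0.51 without Y+ C1, lost at 0.0767 with quantile normalization, 0.0689 with normexp, 0.161 with detected-probe scaling, 0.0827 at median −0.52 without E− C2, 0.0697 without E+ C1, 0.0516 or 0.0519 without E+ Tg1 or Tg2, 0.0606 without Y− C2, 0.0678 without Y− Tg1, 0.24 without Y+ C2 and 0.0713 at median −0.42 without Y+ Tg1); angiogenic sprouting −0.43 (0.318, −0.66 with detected-probe scaling, −0.23 without Y− Tg1 and −0.27 without Y+ Tg1); vascular basement membrane −1.52 (0.318); hemogenic endothelium and stem cell 0.86 (0.488, lost at 0.0584 with quantile normalization, 0.0584 without E− C2, 0.0888 without E+ C2, 0.0516 without E+ Tg1, 0.0527 or 0.0532 without Y− Tg1 or Tg2, 0.118 at median 0.56 without Y+ C1 and 0.0825 or 0.0545 without Y+ Tg1 or Tg2); pan-leukocyte 0.93 (0.318); macrophage −0.64 (0.318, −1.001 with normexp, −0.34 with the strict filter, −0.30 without E+ Tg1 and −0.40 without Y+ Tg2); megakaryocyte and platelet 1.73 (0.318); mesenchymal and mural cell −1.44 (0.318, −0.81 with normexp); endothelial-to-mesenchymal transition −1.02 (0.318, −0.39 with normexp); yolk sac endoderm and liver −0.97 (0.517, −0.39 or −1.78 without Y− Tg1 or Tg2, −0.52 or −1.51 without Y+ C1 or C2 and −0.65 without Y+ Tg1); neural −1.22 (0.318, −0.34 with normexp, −0.67 without E− C1 and −0.74 without E+ C1); epithelial −1.01 (0.355, −0.67 with normexp, −0.65 without Y− Tg1 and −0.44 without Y+ C1); cell cycle 0.46 (0.318, 0.21 with quantile normalization and 0.23 with detected-probe scaling); dissociation stress −0.62 (0.318); interferon response −1.13 (0.355, −0.69 without E+ C2 and −0.66 without Y+ C1); hypoxia and glycolysis 0.63 (0.561, 0.40 with detected-probe scaling, lost at 0.0727 with the strict filter, 0.0932 without E− C1, 0.0697 without E+ C1 and 0.0867 without Y+ C2).

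Single genes with a higher effect in the yolk sac were Etv2 3.43 ± 0.96, Slco4a1 3.68 ± 0.79, Neurl3 3.25 ± 0.58, Srgap3 4.09 ± 0.62, Bin2 2.15 ± 0.19, Clec1b 2.96 ± 0.28, P2rx1 2.18 ± 0.23, Cd48 2.27 ± 0.25 and Myb 2.52 ± 0.41 (highest adjusted p 0.0318 for Etv2). Lower ones were Lama1 −3.82 ± 0.52, Fst −3.70 ± 0.54, Fxyd3 −3.96 ± 0.47, Fbln5 −3.46 ± 0.41, Nrp1 −2.60 ± 0.35, Col4a1 −2.32 ± 0.33, Col4a2 −2.19 ± 0.29, Ccn1 −3.45 ± 0.39, Fos −2.89 ± 0.37, Adgre1 −2.10 ± 0.26 and Tlr4 −2.09 ± 0.28 (highest adjusted p 0.00277 for Fst). With normexp the difference was 2.08 for Etv2, 2.36 for Srgap3, −2.53 for Fxyd3 and −1.39 for Tlr4.

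For the average effect of Tie-2-Etv2, only the real split of 100 drawn called as many genes (real count 11037, highest other 6940). For the gates in controls, fitted as 2 groups, only the real split of 35 called as many (8972, highest other 149). These tallies argue against random grouping only if the arrays of a group are independent, which is not known.

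Of 43 pan-endothelial genes 16 rose in embryo and 28 in yolk sac CD45+ Tie-2-Etv2 cells (for the shifts of the list, estimated-correlation p = 0.16 and 0.595). Admixed CD45− cells of the same genotype are a candidate explanation. The gate was meant to remove such cells, but the purity of the sort was not tested. Such cells, as sampled here, would give each risen gene the same share of admixed RNA. In the embryo 56.2% of the 16 genes that rose excluded the median share (11.1%, genes from 3.18% to 40.8%), and in the yolk sac 46.4% of the 28 genes that rose excluded the median share (32.8%, genes from 4.81% to 238%), which argues against such admixture as the whole cause. A lower share of macrophages would raise markers of every other cell type alike. In the yolk sac the pan-endothelial median was 1.46 (95% bootstrap interval over genes 1.06 to 2.58). Granulocyte and mast cell genes had 2.94 (1.59 to 4.51) and megakaryocyte genes 2.77 (1.37 to 4.94), as that explanation needs. Endoderm and liver genes had −1.29 (−1.39 to −1.15). Without Y+ C1 or C2 this was −0.35 or −2.30, and without Y+ Tg1 or Tg2 −0.45 or −2.24. All stayed negative but outside the interval, which leaves out spread between arrays. A lower macrophage share, a contribution of admixture, more cells of the types that rose, a subset of CD45− cells, and higher expression in CD45+ cells stay open.

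Of 31 pan-leukocyte genes 21 rose in embryo and 28 in yolk sac CD45− Tie-2-Etv2 cells (for the shifts of the list, estimated-correlation p = 0.00363 and 0.0599). Admixed CD45+ cells of the same genotype are a candidate explanation. The gate was meant to remove such cells, but the purity of the sort was not tested. In the embryo 76.2% of the 21 genes that rose excluded the median share (8.11%, genes from 0.385% to 45.4%), and in the yolk sac 60.7% of the 28 genes that rose excluded the median share (50.3%, genes from 1.54% to 193%). These values argue against admixture of the CD45+ cells as sampled as the whole cause. Part of the rise, a subset of CD45+ cells, and expression in CD45− cells of the transgenic animals, the biological explanation that the design gives, stay open.

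Of 43 pan-endothelial genes 32 fell in yolk sac CD45− Tie-2-Etv2 cells (for the shift of the list, estimated-correlation p = 0.10), for which a lower share of endothelial cells may be the cause. It would lower each gene alike only if the cells in their place lacked these transcripts, which was not tested. Of 43 genes, 48.8% had a 95% interval that excluded the median of −1.99, from Emcn at −3.6 to Tal1 at 2.8. A lower share, in whole or part, and an effect of the transgene on endothelial cells, stay open.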

How the results depend on the processing

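No test here was chosen after the results were seen, since all alternatives were fixed before the data were examined. Of the values of named genes 4672 kept direction and side of the threshold, 132 lost the call, 10 gained one and 11 reversed. Of the list results 5356 kept both, 315 lost and 145 gained a call and 3 reversed. Of the counts of genes 156 stayed within 1.5 times, 23 were lower and 2 higher. 202 of 279 gene values and 96 of 290 list results were the same under all alternatives run. Signal over background limits the values of dim genes.

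Counts beyond 1.5 times the reported ones were as follows. With normexp they were 1126 for embryo CD45+ cells (reported 744) and 127 for the tissues in CD45+ controls (reported 422). Without a filter on dim probes the latter was 224, and with the strict filter 140, with 176 for embryo CD45− cells (reported 317). On the 4 arrays of a comparison they were 134 for embryo CD45−, 0 by limma for embryo CD45+ (2892 at an unadjusted p under 0.05) and 4510 for yolk sac CD45+ cells (reported 8014). On the slide's 8 arrays embryo CD45+ cells gave 413. On the embryo arrays alone they were 458 for the average (reported 11037), 166 for the difference between gates (reported 3862) and 7882 for the gates in controls (reported 12178). These used fewer arrays.

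Leaving out an array gave ranges of embryo CD45+ 284 (without E+ Tg2) to 931 (without E+ C2); yolk sac CD45− 6609 (without Y− Tg1) to 8901 (without Y− Tg2); yolk sac CD45+ 5266 (without Y+ Tg1) to 7495 (without Y+ C2); the difference between tissues 2951 (without E+ Tg1) to 5494 (without Y+ C2); the tissues in CD45− controls 875 (without Y− C2) to 2506 (without E− C2); the tissues in CD45+ controls 270 (without Y+ C1) to 873 (without Y+ C2). Camera with an estimated correlation called 22 of the 155 list results that camera called at the preset one. Fry called 116 of 290, without 50 of those and with 11 others.

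Reversed values were these, and the cause was not tested except where probes differed. Ptprc in embryo CD45− cells was 0.13 with normexp and −0.62 (without E− C2) to 0.0608 (without E− C1), but was not well above background in either genotype, so no direction can be read. Tek there was −0.30 (without E− Tg2) to 0.18 (without E− Tg1). Kdr in embryo CD45+ cells was 0.00399 with detected-probe scaling, 0.99 as the mean over its probes, and −0.22 (without E+ C2) to 0.16 (without E+ C1). Kdr in yolk sac CD45+ cells was 1.85 and Runx1 0.20 as the mean over probes, and Kdr −0.53 (without Y+ C2) to 0.14 (without Y+ C1). On the embryo arrays alone neural genes in the average had a median of 0.12 and cell cycle genes in the difference between gates −0.00621, where the direction of the test turned. Interferon response genes between tissues in CD45+ controls ranged from −0.44 (without E+ C2) to 1.47 (without Y+ C2).

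With the replicate number as a block (replicate block) the counts were 328 for embryo CD45−, 1034 for embryo CD45+, 11485 for yolk sac CD45−, 9001 for yolk sac CD45+, 12241 for the average, 4405 for the difference between gates, 6283 for the difference between tissues, 13096 for the gates in controls, 3513 for the tissues in CD45− controls and 492 for the tissues in CD45+ controls, with 151 list results called. Deviations of samples with the same number correlated at 0.267 (embryo CD45−), 0.0239 (embryo CD45+), 0.0824 (yolk sac CD45−) and −0.00544 (yolk sac CD45+), and over 28 pairs of groups at −0.0472 to 0.385, 8 of them over 0.1. The numbers were not taken to pair the samples, and whether they mark a shared litter or day is not given in the sources used here.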

Other observations

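The comparison of gates across genotypes in the last paragraph was chosen only after the results were seen.

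Lists not described above were these. Of primitive erythroid genes, 0 of 7 rose and 0 fell (0 and 0 adjusted over the list alone) in embryo CD45− cells, with 1 higher and 0 lower by limma at an unadjusted p under 0.05. Their median was 0.66 (adjusted p = 0.00989, estimated-correlation p = 0.267; lost at adjusted p = 0.134 at median 0.31 without E− C1 and 0.265 at median 0.42 without E− Tg2). Lymphoid genes passed in none of the 10 comparisons by camera (smallest adjusted p = 0.162, for the difference between gates, median 0.21), nor did ETS family factors (smallest adjusted p = 0.0665, for yolk sac CD45−, median −0.34; adjusted p = 0.00829 with the strict filter and 0.031 with the probe mean) or p53 response and apoptosis genes (smallest adjusted p = 0.121, for embryo CD45−, median −0.35; adjusted p = 0.00945 with normexp and 0.0185 without E− C2).

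Of blood-brain-barrier endothelial genes, 1 of 17 rose and 10 fell (1 and 10 adjusted over the list alone) in yolk sac CD45− cells. Their median was −2.34 (adjusted p = 0.00133, estimated-correlation p = 0.10; −0.85 with normexp, lost at adjusted p = 0.399 at median 0.0943 with the strict filter).

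Across genes, which are not independent, arrays of the 2 gates correlated at a mean of 0.871 in embryo controls and 0.901 in embryo Tie-2-Etv2 samples. In the yolk sac the means were 0.868 and 0.955. These values were not tested.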
